A study of Mus musculus with 4 samples.

How the data were processed

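Total RNA of Mll1-/- and wild-type mouse embryonic fibroblasts, both described as cell lines grown in serum-containing medium, was labelled with Cy3 and Cy5 and hybridised to Agilent 4x44k mouse arrays, per the labels' protocols. Each of the 4 arrays held both genotypes, and dyes were swapped on 2 of them. The submitters' processing notes name Agilent Feature Extraction 10.1.1. The deposited table holds, per feature and array, one value that was treated as the log2 ratio of the 2 channels made by the authors. Background correction, normalization, log base, the meaning of blank values and the direction of the ratio are not given in the sources used here. Base 2 was inferred because the widest values would exceed a scanner's range on a log10 or natural-log scale. Direction stays likely, not certain. The scale within an array was kept as deposited. Array medians over all features were −0.01, 0.03, −0.02 and 0.02.

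The 4 columns correlated positively across the 29054 features with a value on every array, although dyes were swapped, so the values had already been turned one way. Arrays of the same dye orientation had r = 0.83 and 0.85, and arrays of opposite orientation had r from 0.72 to 0.78. Features were named through the platform's annotation. It gave 33653 features 1 gene symbol, 56 several and 11309 none, and 33517 of the first kind had a gene ID that matched a RefSeq gene table of assembly GRCm38.p6. That table was used for chromosome membership and for the order of neighbouring genes, and no coordinates are given because the array annotation names no genome build here. A reference genome was not used here. Features with several symbols or none were left out of the tests, as were features with a blank on any array. A planned filter on values of exactly 0 removed nothing, since no array held such a value. This left 24012 features of 14222 genes, out of 19087 genes with a singly named feature. Features of one gene were averaged, which concerned 5983 genes. In 328 genes single features passed the threshold in opposite directions. None of the genes chosen by the naming rule is among them.

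Genotype was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the log2 ratios, with a gene-specific dye term beside the genotype term, which left 2 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05, and a change of at least 2-fold meant an absolute log2 ratio of at least 1. Errors in the text are SDs over the 4 arrays. The tests use the moderated standard errors of the fitted model instead. Gene lists were fixed before the data were examined, and tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 24 lists. They cover Hox genes, other patterning transcription factors, H3K4 methyltransferase complexes, Polycomb group genes, cell cycle, CDK inhibitors and p53 targets, extracellular matrix, smooth muscle, interferon response, NF-kB and inflammation, Wnt pathway, imprinted genes, circadian clock, stress response, housekeeping, sex chromosomes, and markers of epithelium, endothelium, macrophages and blood, nerve and glia, skeletal and cardiac muscle, adipocytes, cartilage and bone, and pluripotent and germ cells. The named genes are Kmt2a, the 8 largest rises and 8 largest falls past the threshold with one sign on all arrays (predicted genes, clones and receptor models of olfaction skipped), and in each list up to 2 genes past the threshold each way, or up to 4 for Hox genes. Names outside this rule are given as such.

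The labels number the arrays but do not say which share an RNA extract. The spread between arrays 1 and 2 and arrays 3 and 4 had a median absolute deviation of 0.104, against 0.0365 for the other pairing of opposite dyes and 0.124 between dye orientations. The SDs of the same contrasts were closer, at 0.198, 0.160 and 0.201. On simulated data with 200 changed genes among 14222 and independent arrays, the model called 121 genes, 5 of them wrongly, and recovered 41.8% of 1.5-fold, 50.7% of 2-fold and 81.8% of 4-fold changes. When the simulated pairs shared a deviation, it called 142 genes, 29 of them wrongly, and 13.1% of unchanged genes had an unadjusted p under 0.05. Averaging the pairs called 0 genes in either simulation, and 5.81% of unchanged genes then had an unadjusted p under 0.05 where pairs shared a deviation (limma). In the real data the main fit called 8415 genes, and averaging the pairs called 2690 higher and 2923 lower. The simulated share of changed genes is thus far from the real one, so the simulated recovery and false calls are not rates for the real data. The alternatives tried were no dye term, centring or scaling of the arrays, other zero filters, each probe by itself, a robust variance prior, both pairings of arrays averaged, each array left out, and 4 alternatives added after seeing the data. Scaling was done with limma's normalizeMedianAbsValues. With each probe by itself, only the middle feature by log2 ratio, or the lower of the middle 2, was read out for each named gene.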

Results

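RNA from mouse embryonic fibroblasts lacking Mll1 (Mll1-/-) was hybridised directly against RNA from wild-type fibroblasts on 4 two-colour whole-genome expression arrays. Mouse embryonic fibroblasts are connective-tissue cells grown out of embryos. Mll1, now named Kmt2a, encodes a histone H3 lysine 4 methyltransferase that is known to maintain the expression of Hox genes during development. The knockout RNA carried Cy5 on arrays 1 and 3 and Cy3 on arrays 2 and 4. All 4 arrays form a single group, Mll1-/- against wild type, and each array gives a log2 ratio per feature. Of 45018 features, 33685, 33417, 31603 and 37425 held a value on arrays 1 to 4, and 29054 held a value on all 4. The arrays' median log2 ratios over all features were −0.01, 0.03, −0.02 and 0.02. No channel intensities were used here, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision.

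The direction of the deposited ratios is not stated. It is likely Mll1-/- over wild type, because the sample titles name the mutant first and because the targeted gene, Kmt2a, is lower that way. The fall of Kmt2a is therefore part of the basis for the direction and not an independent check of it. If the ratios run the other way, every rise and fall given here changes places. Kmt2a had the same sign on every array, with a log2 ratio of −1.24 ± 0.42 (SD, n = 4), a 2.37-fold difference (limma, adjusted p = 0.0138), with array values of −1.61, −1.58, −1.01 and −0.78. A single feature measured Kmt2a, and the labels do not say which part of the gene is missing, so this feature may lie outside it and then checks nothing. Log base 2 was inferred from the range of the values.

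The Mll1-/- and wild-type fibroblasts differed widely in transcript levels. Genotype and cell line were compared together, so any difference given here may stem from the line and not from loss of Mll1. The largest rises in the knockout were those of Ifi202b, an interferon-inducible gene whose level is known to differ between inbred mouse strains (log2 ratio 9.09 ± 0.80, SD over the 4 arrays, as for all errors that follow), and of Pygl, the liver form of glycogen phosphorylase (7.98 ± 0.51). Tbx3, a T-box transcription factor of limb patterning, rose by 7.46 ± 2.91, Map2, a neuronal microtubule-associated protein, by 6.53 ± 0.47, and Acot1, an acyl-CoA thioesterase, by 6.31 ± 0.74. Fhl1, a LIM-domain protein abundant in muscle, rose by 6.31 ± 0.34, Mmp16, a membrane-type matrix metalloproteinase, by 6.24 ± 0.56, and Snap91, a clathrin assembly protein of synapses, by 6.14 ± 1.41. The largest falls were those of Efemp1, the extracellular matrix protein fibulin-3 (−7.42 ± 0.15), the complement inhibitor C4bp (−6.88 ± 0.29) and Wdr72 (−6.68 ± 2.31). Il20ra, a cytokine receptor chain, followed at −6.57 ± 0.36, the selenium transport protein Selenop at −6.55 ± 0.35 and Hoxc9 at −6.53 ± 0.16. Rspo2, a secreted enhancer of Wnt signalling, was at −6.52 ± 0.29 and Mgp, an inhibitor of matrix calcification, at −6.50 ± 0.55. All 16 were chosen for passing the threshold with the same sign on every array. Their limma adjusted p-values ran from 0.000426 to 0.00995. The ratios of Tbx3 and Wdr72 were the least even. Tbx3 stood at 11.77 on array 1 and between 5.48 and 6.52 on the others, and was 6.15 without array 1. Wdr72 stood at −10.07 on array 2 and between −4.86 and −5.98 on the others, and was −7.70 without array 4, where the dye term gives array 2 more weight. Ratios of this size can rest on a channel close to background, which cannot be seen here.

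**Figure D1:**
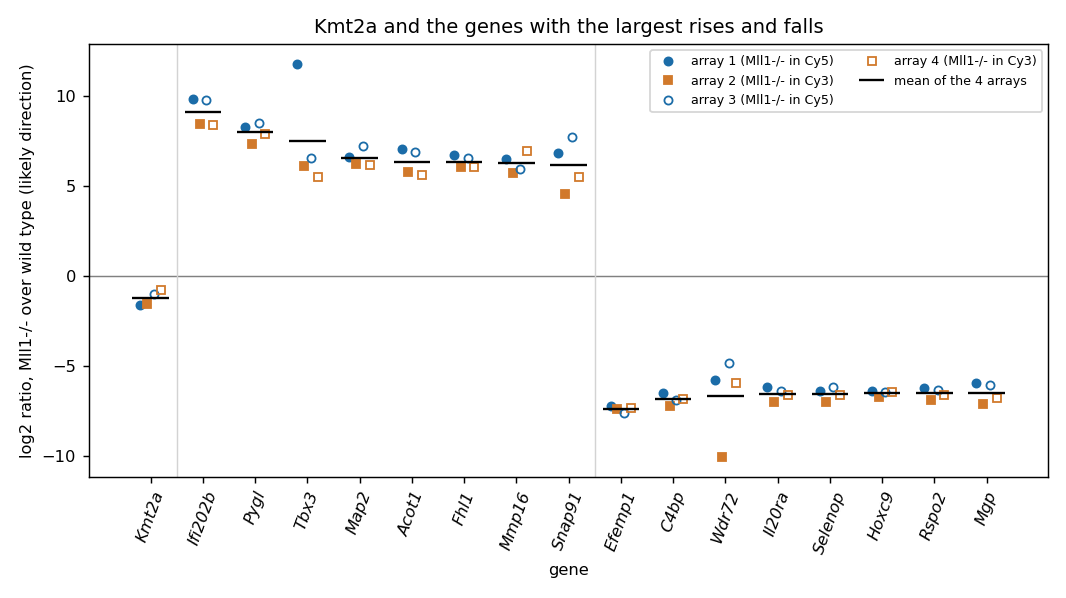
Log2 ratio (y axis) of Kmt2a and of the 8 genes with the largest rises and the 8 with the largest falls (x axis). Each point is 1 of the 4 arrays, with circles for Mll1-/- RNA in Cy5 and squares for Mll1-/- RNA in Cy3, and the bar is their mean. The rule that chose the rises and falls puts all points of such a gene on one side of 0, and those of Kmt2a lie on one side too. Array 1 stands apart for Tbx3 (11.77) and array 2 for Wdr72 (−10.07).

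Across the 14222 genes with a value on all 4 arrays, 4140 (29.1%) were higher and 4275 (30.1%) lower in Mll1-/- fibroblasts (limma with a gene-specific dye term, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were fewer, with 896 genes higher and 1147 lower. Of the 8415 genes past the threshold, 8144 had the same sign on all 4 arrays. The median SD over the arrays was 0.17 and the median absolute log2 ratio 0.34. No gene's dye term passed the threshold in limma, but 2105 genes (14.8%) had an unadjusted p under 0.05 for it, a larger share than chance gives. The labels do not say that the arrays came from separate cultures or extracts, so p-values measure the spread between these arrays, which may be technical. By median absolute deviation, though less so by SD, arrays 1 and 2 deviated more alike than the other pairing of opposite dyes, as did arrays 3 and 4. With each of these pairs averaged into 1 value 2690 genes were higher and 2923 lower. The count of higher genes was 2665 without array 1 and 2532 without array 2.

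Hox genes, the textbook targets of MLL1, were lower as a group. Of 39 Hox genes, 22 had a value on all arrays, of which 15 fell and 4 rose (5 rose and 15 fell when adjusted over the list alone), with a median log2 ratio of −0.85. The largest falls were Hoxc9, 92.3-fold (−6.53 ± 0.16), Hoxc10, 17.3-fold (−4.11 ± 0.81), Hoxc6, 11.04-fold (−3.46 ± 0.18), and Hoxb5, 9.83-fold (−3.30 ± 0.25). The 4 that rose were Hoxd9, 14.5-fold (3.85 ± 1.08), Hoxa4 (1.24 ± 0.19), Hoxb4 (0.72 ± 0.36) and Hoxb2 (0.45 ± 0.17). By cluster, all 6 tested Hoxc genes fell, with a median of −3.09. In the Hoxb cluster 5 of 8 fell and 2 rose, in the Hoxa cluster 4 of 7 fell and 1 rose, and Hoxd9 was the single Hoxd gene tested. Hoxa5 (−0.13), Hoxa6 (0.03) and Hoxb8 (0.37), named here because they did not pass, make up the rest. The list was lower than other genes by camera with its preset inter-gene correlation (adjusted p = 0.0305), but the call was lost with an estimated one (adjusted p = 0.846 with an estimated correlation). It was also lost with arrays 1 and 4, and 2 and 3, averaged (adjusted p = 0.0848) and with each gene taken relative to its chromosome's median (adjusted p = 0.0545). Between the array pairs the list differed (camera, adjusted p = 0.00873), but not with an estimated correlation (adjusted p = 0.946 with an estimated correlation). The list medians were −0.87 on arrays 1 and 2 and −0.84 on arrays 3 and 4. Per gene, the median difference of the first pair from the second was −0.17.

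**Figure D2:**
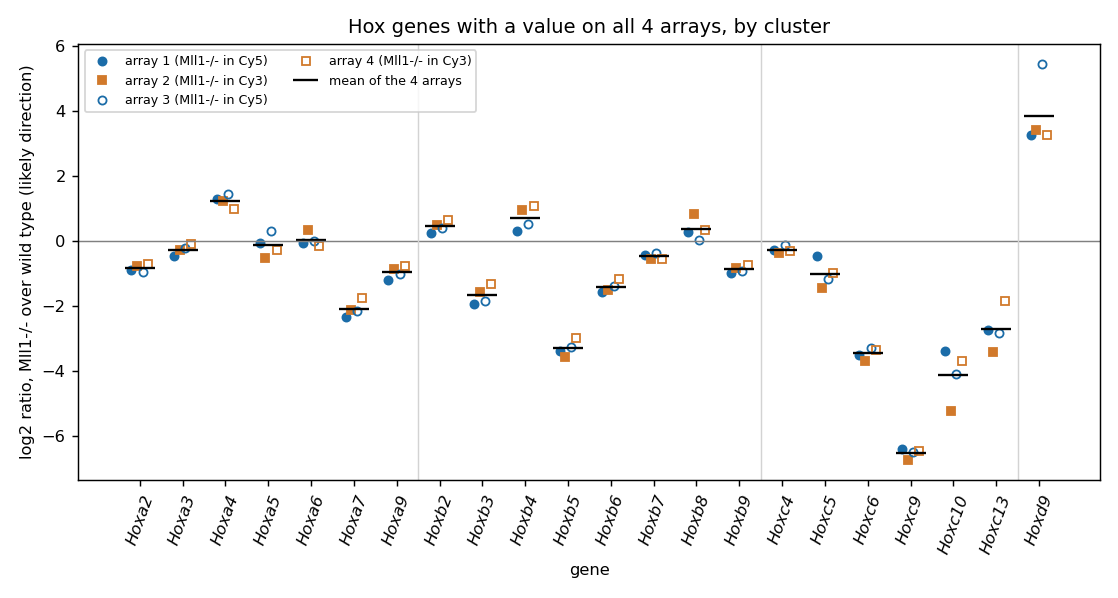
Log2 ratio (y axis) of the 22 Hox genes with a value on all 4 arrays (x axis, ordered by cluster, with grey lines between the clusters). Each point is 1 array, with circles for Mll1-/- RNA in Cy5 and squares for Mll1-/- RNA in Cy3, and the bar is the mean, which runs from −6.53 for Hoxc9 to 3.85 for Hoxd9. All 6 Hoxc genes lie below 0.

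Other patterning transcription factors changed in both directions. Of 39 tested, 9 rose and 21 fell, the same counts as when adjusted over the list alone, with a median of −0.50. Msx2, a homeobox factor of limb and skull, rose 68.5-fold (6.10 ± 0.79) beside Tbx3, while Pax9, a paired-box factor of the skeleton and teeth, fell 85.9-fold (−6.42 ± 0.20) and Foxc1, a forkhead factor of mesenchyme, fell 14.7-fold (−3.88 ± 0.02). The list as a whole did not pass (camera, adjusted p = 0.120).

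Contractile genes of smooth muscle rose together. Of 18 tested, 15 rose and 1 fell, also when adjusted over the list alone, with 12 of them at least 2-fold higher and a median of 1.46. Myl9, the regulatory light chain of smooth muscle myosin, rose 27.9-fold (4.80 ± 0.20) and Cnn1, the actin-binding protein calponin, 19.6-fold (4.29 ± 0.23). Des, an intermediate filament protein of muscle, was the exception at −0.31 ± 0.26, a call lost without the dye term (adjusted p = 0.0732) and without array 1, 3 or 4 (highest adjusted p = 0.0757), and with arrays 1 and 2, and 3 and 4, averaged (0.0679). Camera placed the list above other genes (adjusted p = 2.04e-06), but not once the correlation between genes was estimated (adjusted p = 0.846 with an estimated correlation). Skeletal and cardiac muscle markers showed 5 rises and 2 falls among 13, in the list alone too, with a median of 0.09 (camera, adjusted p = 0.248). Troponin T of the heart, Tnnt2, rose 9.11-fold (3.19 ± 0.29) and skeletal actin, Acta1, 5.63-fold (2.49 ± 0.15), whereas the transcription factors Mef2c (−1.24 ± 0.47) and Myog (−0.79 ± 0.30) fell. Their calls were lost without array 2 or 4 for Mef2c (highest adjusted p = 0.0751) and without array 3 for Myog (0.0505). With each probe tested by itself, the middle one of the 9 Myog features did not pass (−0.56, limma adjusted p = 0.144), and the others were not read out. With arrays 1 and 2, and 3 and 4, as a random block the calls of Mef2c and Myog were both lost (0.110 and 0.0836).

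Extracellular matrix genes mostly fell. Of 57 tested, 31 fell and 11 rose (32 and 12 when adjusted over the list alone), 20 of them at least 2-fold lower, with a median of −0.39. Beside Efemp1, the matricellular protein Postn fell 22.4-fold (−4.49 ± 0.34). The fibrillar collagen Col3a1 rose 4.81-fold (2.27 ± 0.53), as did the collagen cross-linking enzyme Loxl2, 3.32-fold (1.73 ± 0.21). Camera gave an adjusted p = 0.0305 with the preset correlation and an adjusted p = 0.846 with an estimated correlation. The list's camera call ended with arrays 1 and 4, and 2 and 3, averaged (adjusted p = 0.0848), and when each probe was tested by itself its direction turned (adjusted p = 0.989).

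Adipocyte markers fell in 5 of 7 genes and rose in 1, also when adjusted over the list alone, with a median of −1.33. Angiotensinogen, Agt, fell 25.8-fold (−4.69 ± 0.25) and the fatty acid-binding protein Fabp4 19.6-fold (−4.29 ± 0.20), while lipoprotein lipase, Lpl, rose 2.44-fold (1.29 ± 0.53). Camera gave an adjusted p = 0.0422, and an adjusted p = 0.846 with an estimated correlation. Its call was lost with the arrays scaled to equal spread (adjusted p = 0.0692), with arrays 1 and 4, and 2 and 3, averaged (0.0862), without array 3 (0.0520) and without array 4 (0.0517). Cartilage and bone markers fell in 5 of 11 genes and rose in 1, in the list alone too (median −0.31, camera adjusted p = 0.248). Osteocalcin, Bglap, fell 4.01-fold (−2.00 ± 0.26) along with Mgp, and alkaline phosphatase, Alpl, rose 4.35-fold (2.12 ± 1.09). The calls of Lpl without array 1 or 2 (highest adjusted p = 0.0610) and of Alpl without array 2 or 4 (0.0945) were lost, the latter also with the array pairs as a random block (0.0876).

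Inflammatory and interferon-response genes fell more often than they rose, without their lists passing the test. Of 27 NF-kB and inflammatory genes, 15 fell and 5 rose, in the list alone too (median −0.58, camera adjusted p = 0.0583). The acute-phase protein gene Saa3 fell 13.9-fold (−3.80 ± 0.26) and the cytokine gene Il6 9.08-fold (−3.18 ± 0.14), while the chemokine genes Cxcl12 (0.95 ± 0.37) and Cx3cl1 (0.82 ± 0.46) rose. Of 32 interferon-response and MHC class I genes, 17 fell and 5 rose (17 and 6 when adjusted over the list alone, median −0.38, camera adjusted p = 0.120). Parp14 fell 9.49-fold (−3.25 ± 0.37) and the guanylate-binding protein gene Gbp2 4.23-fold (−2.08 ± 0.17), while Oasl1 (1.77 ± 0.94) and the immunoproteasome subunit gene Psmb8 (1.56 ± 0.14) rose. The calls of Oasl1 (without array 1 or 3, highest adjusted p = 0.0980), Cxcl12 (without array 3 or 4, 0.0646) and Cx3cl1 (without array 1, 2 or 4, 0.111) were lost. With each probe tested by itself, the lower of the 2 Cxcl12 features did not pass (0.52, limma adjusted p = 0.117), and the other was not read out. Oasl1 (0.108) and Cx3cl1 (0.0515) lost the call with the array pairs as a random block, and Cx3cl1 with these pairs averaged (0.0700). Both lists differed between the array pairs. The inflammatory median was −0.54 on arrays 1 and 2 and −0.81 on arrays 3 and 4 (camera for the difference, adjusted p = 0.000884), and the interferon median was −0.26 and −0.75 (adjusted p = 0.00038). Per gene, the median difference of the first pair from the second was 0.20 for the inflammatory list and 0.22 for the interferon list. With an estimated correlation no list differed between the pairs (adjusted p = 0.946 with an estimated correlation).

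Cell cycle genes rose in 24 of 45 cases and fell in 11 (25 and 12 when adjusted over the list alone), with a small median of 0.19 (camera, adjusted p = 0.120). The mitotic cyclin Ccnb2 rose 2.45-fold (1.29 ± 0.08) and the replication factor Cdc45 1.78-fold (0.83 ± 0.27), while E2f2, a transcription factor of the G1/S transition, fell 3.44-fold (−1.78 ± 0.15) and thymidylate synthase, Tyms, 1.63-fold (−0.70 ± 0.41). Among 25 CDK inhibitors and p53 targets, 14 fell and 6 rose, in the list alone too (median −0.26, camera adjusted p = 0.120). Cdkn1b fell 3.55-fold (−1.83 ± 0.25) and Cdkn2c 2.61-fold (−1.38 ± 0.09). Both encode CDK inhibitors known as targets of menin and MLL1. Cdkn1c, another CDK inhibitor, rose 5.78-fold with a wide spread (2.53 ± 1.42), and was 1.73 without array 2, and Pmaip1, the p53 target Noxa, rose 4.18-fold (2.07 ± 0.40). Leaving out 1 array ended the calls of Cdkn1c (array 1, 2 or 3, highest adjusted p = 0.141) and Tyms (array 1 or 3, 0.106), as did a random block for arrays 1 and 2, and 3 and 4 (0.286 and 0.115). Cdkn1c also lost it in 4 other settings, with adjusted p-values from 0.0501 to 0.110. This list also differed between the array pairs (camera, adjusted p = 0.0129), but not with an estimated correlation (adjusted p = 0.946 with an estimated correlation). Its medians were −0.33 on arrays 1 and 2 and −0.25 on arrays 3 and 4. Per gene, the median difference of the first pair from the second was −0.11.

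Genes of the H3K4 methyltransferase complexes showed 7 rises and 4 falls among 21 tested, in the list alone too. Wdr82 (0.62 ± 0.10) and Wdr5 (0.62 ± 0.12), both subunits of such complexes, rose 1.54-fold, and Kmt2e, an MLL family member, fell 2.04-fold (−1.03 ± 0.27). Tasp1, the protease that cleaves MLL1, fell 1.95-fold (−0.96 ± 0.15). Polycomb group genes rose in 6 and fell in 6 of 24 cases, in the list alone too. Pcgf5 (1.03 ± 0.31) and Phf19 (0.98 ± 0.06) rose, and the ubiquitin ligase Rnf2 (−0.73 ± 0.07) and Phc1 (−0.72 ± 0.08) fell. Neither list moved as a whole (camera, adjusted p = 0.932 and 0.970). The H3K4 list had a median and a mean below 0 (−0.01 and −0.04) and a camera direction above it, and the Polycomb list a median of −0.03, a mean of 0.05 and a camera direction below 0.

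Wnt pathway genes fell in 15 and rose in 6 of 32 cases (16 and 7 when adjusted over the list alone), with a median of −0.28 (camera, adjusted p = 0.122). Beside Rspo2, the secreted protein Dkk3 fell 61.6-fold (−5.95 ± 0.48), and the intracellular Wnt antagonists Nkd2 (2.48 ± 0.06) and Nkd1 (1.80 ± 0.60) rose, the call of Nkd1 being lost with the array pairs as a random block (adjusted p = 0.0861). Imprinted genes fell in 10 and rose in 6 of 23 cases, in the list alone too (median −0.09, camera adjusted p = 0.708). The neighbouring maternally expressed noncoding RNAs Rian (−4.60 ± 0.49) and Meg3 (−3.56 ± 1.27) both fell, the latter −4.27 without array 4, while Mest (3.84 ± 1.78, and 3.06 without array 2) and Phlda2 (3.11 ± 0.56) rose. Mest lost its call without array 1 (adjusted p = 0.0658) and Meg3 without array 3 (0.0574) and with the array pairs as a random block (0.110).

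Circadian clock genes showed 6 rises and 5 falls among 17, in the list alone too, with a median of 0.09 and a mean of −0.11 (camera direction upward, adjusted p = 0.970). Cry2 (0.92 ± 0.13) and Bhlhe41 (0.61 ± 0.17) rose, and Hlf (−2.54 ± 0.10) and Per3 (−0.55 ± 0.34) fell. Bhlhe41 lost its call without array 2 or 4 (highest adjusted p = 0.0600) and Per3 without array 1 or 3 (0.109), with arrays 1 and 4, and 2 and 3, averaged (0.0594) and with arrays 1 and 2, and 3 and 4, as a random block (0.169). Stress-response genes rose in 9 and fell in 10 of 22 cases, in the list alone too, with a median of −0.12 and a mean of 0.04 (camera direction downward, adjusted p = 0.932). The chaperone genes Hspa1a (2.96 ± 0.11) and Hspb1 (2.32 ± 0.30) rose and the immediate-early genes Fos (−1.61 ± 0.51) and Egr1 (−1.56 ± 0.18) fell. Of 12 housekeeping genes 5 rose and 2 fell, in the list alone too (median 0.01, camera adjusted p = 0.836), with Tfrc (1.001 ± 0.18) and Actb (0.64 ± 0.10) up and Gusb (−0.76 ± 0.09) and Hprt (−0.43 ± 0.26) down.

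None of the lists of epithelial, endothelial, macrophage and blood, neural or pluripotency markers passed camera, although single members changed. Of 9 neural and glial markers 5 rose and none fell, in the list alone too (median 0.74, camera adjusted p = 0.123). They included Map2 and the intermediate filament gene Nes, which rose 8.28-fold (3.05 ± 0.16). Among 11 epithelial markers 3 fell and 1 rose, in the list alone too. Trp63 fell 27.3-fold (−4.77 ± 0.30) and the keratin gene Krt7 7.07-fold (−2.82 ± 0.14), and Cldn3 rose (0.80 ± 0.16). The epithelial list had a median of 0.02 and a mean of −0.74 (camera direction downward, adjusted p = 0.804). Of 11 endothelial markers 6 fell and 4 rose, in the list alone too (median −0.39, camera adjusted p = 0.836). Flt1 (1.84 ± 0.41) and Robo4 (1.22 ± 0.51) rose and Sox17 (−2.01 ± 0.38) and Vwf (−1.38 ± 0.25) fell, with the call of Robo4 lost without array 1 or 3 (highest adjusted p = 0.0798). Macrophage and blood markers fell in 3 and rose in 2 of 10 cases, in the list alone too. The lysozyme genes Lyz2 (2.27 ± 0.32) and Lyz1 (2.09 ± 0.23) rose, and Cd14 (−3.78 ± 0.12) and Hba-a1 (−1.61 ± 0.24) fell. The macrophage and blood list had a median of 0.03 and a mean of −0.06 (camera direction downward, adjusted p = 0.970). Of 5 pluripotency and germline markers only Dppa5a changed, rising 4.27-fold (2.09 ± 0.33), in the list alone too (median 0.25, camera adjusted p = 0.708).

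Sex chromosome markers were largely blank. Features of the Y-linked genes Eif2s3y, Kdm5d, Uty and Usp9y held 3 of 28 possible values, all on array 4. Of 3 markers tested, Zfy2 rose slightly (0.32 ± 0.22, limma adjusted p = 0.0398), a call lost when adjusted over the list alone and with any 1 array left out (highest adjusted p = 0.135), with either pairing of arrays averaged (0.0538 and 0.0968), with values on 3 or 4 arrays (0.0502) and with the pairs as a random block (0.256). Xist, the RNA that silences an X chromosome, had a log2 ratio of −0.32 that did not pass (adjusted p = 0.143). Most Xist features stood lower on arrays 1 and 2 (from −0.37 to −0.78) than on arrays 3 and 4 (from −0.003 to −0.22). The remaining Xist feature was uneven (−0.20, −0.93, 0.43 and −0.42 on arrays 1 to 4). Xist and the Y-linked genes with blank features are named outside the naming rule. The list had a median of −0.04, a mean of −0.02 and an upward camera direction (adjusted p = 0.970).

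**Figure D3:**
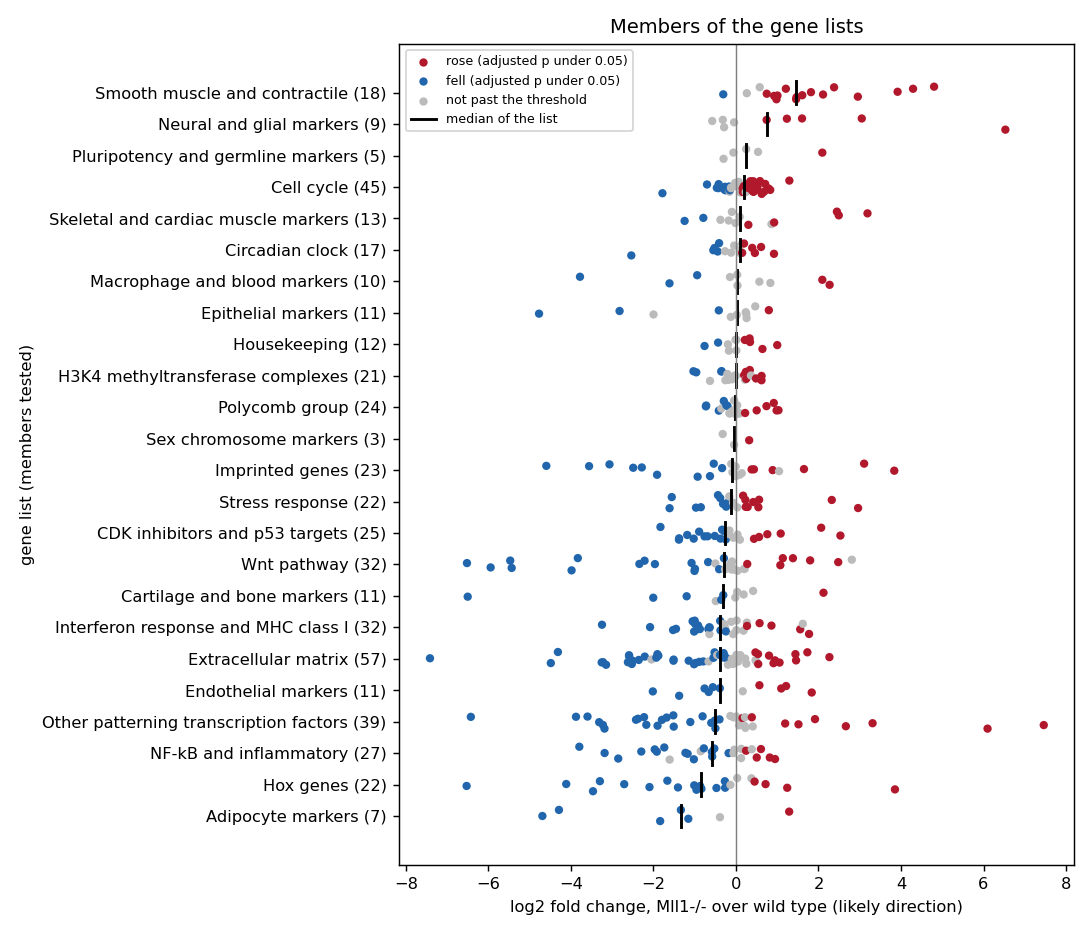
Log2 fold change (x axis) of every tested member of the 24 gene lists (y axis, ordered by median, with the number tested in brackets). Each point is 1 gene, red where it rose, blue where it fell and grey where it did not pass the threshold of 0.05 on the adjusted p, and the black bar is the list's median, from −1.33 for adipocyte markers to 1.46 for smooth muscle genes.

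Of the 24 lists, 4 passed camera's test with the preset correlation (Hox genes, extracellular matrix, smooth muscle and adipocyte markers) and 0 with an estimated one. The estimate rests on 2 residual degrees of freedom, and with it 0 of 20 chromosomes passed either. It could hardly pass any list here, so a call lost under it leaves the question undecided. Fry, which asks whether a list's genes move on balance one way, without comparing them with other genes, passed 17 lists, and all 24 passed its test for change in either direction.

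Genes of chromosome 14 were lower as a whole, a comparison made after the values were seen. Of 487 tested genes on this chromosome, 352 (72.3%) fell and 35 rose, with a median log2 ratio of −0.70 against 0.01 on the other chromosomes. The median lay between −0.72 and −0.69 on each of the 4 arrays. Chromosome 14 held 3.42% of tested genes and 12.5% of those at least 2-fold lower (Fisher's exact test, odds ratio 5.28, two-sided p = 2.60e-45, across genes, which are not independent). Camera gave an adjusted p = 2.71e-16 over the chromosomes, and an adjusted p = 0.303 with an estimated correlation. Of the other chromosomes, 12 also passed with the preset correlation, 6 above 0 and 6 below, with chromosome 16 next (adjusted p = 1.66e-05), and with an estimated correlation 0 of 20 passed. No other chromosome's median was farther from 0 than that of chromosome 16, at 0.29. The extracellular matrix list holds 3 tested genes of chromosome 14, one of which is Loxl2, and the Hox and smooth muscle lists hold 0.

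**Figure D4:**
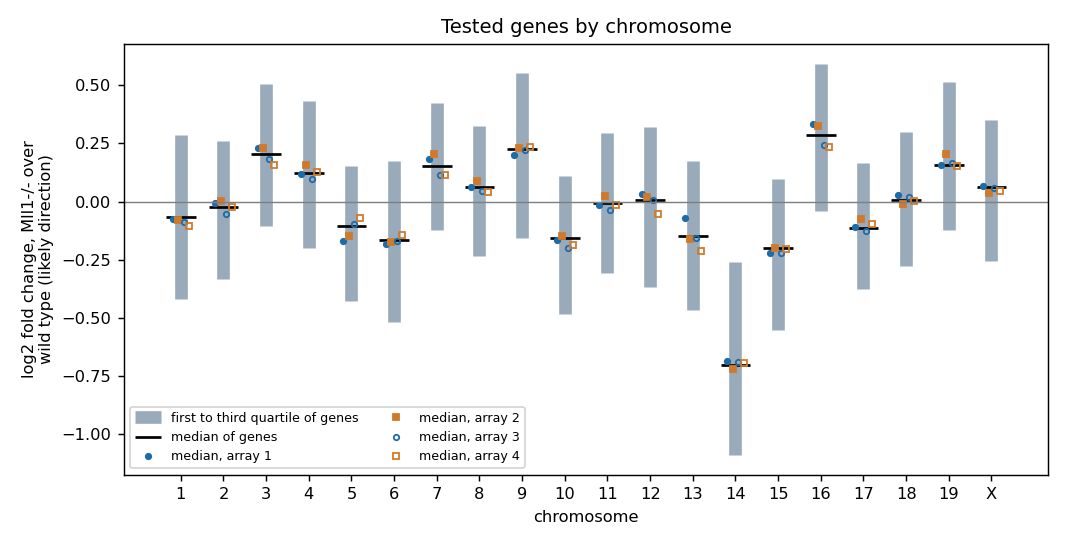
Log2 fold change (y axis) of tested genes on each chromosome (x axis). Bars run from the first to the third quartile, black lines are medians over genes, and points are the medians on each of the 4 arrays (circles for Mll1-/- RNA in Cy5, squares for Mll1-/- RNA in Cy3). Chromosome 14 lies at −0.70, and all other medians lie between −0.20 and 0.29.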

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

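All tests of explanations in this part were chosen after the result was seen, except those on strongly changed genes, on single arrays or dyes, and on a different culture behind each pair of arrays. In 7 of 123 values tested over the 4 arrays, 1 array stood apart from the other 3 by Dixon's ratio, close to the 5% that chance gives. Tbx3 stood at 11.77 on array 1. Hoxd9 stood at 5.46 on array 3 and between 3.26 and 3.43 on the others. Tyms stood at −0.10 on array 4 and Per3 at −0.038 on array 4, both farther below 0 on the other arrays. Parp14 stood at −3.79 and Rian at −5.33 on array 2. Lyz1 stood at 2.44 on array 2 and between 1.96 and 1.99 on the others.

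The lower level of chromosome 14 genes was not the work of a few of them: without genes changed 2-fold or more, the median of its remaining 333 genes was −0.49, against 0.02 for other such genes. It was not due to 1 array or dye orientation, as the highest array median was −0.69, but chance was not excluded: 0 of 10000 random sets of as many genes had a median as far from 0, yet 12 of 19 other chromosomes also lay beyond all such sets. All runs of 30 neighbouring tested genes (100%) had a median below −0.30, which fits fewer copies of the chromosome in the Mll1-/- line as a hypothesis. With a median of −0.70 for the whole chromosome, such runs were likely in any gene order. They show that no stretch was spared, and cannot tell a loss of copies from falls scattered over the chromosome. Smaller shifts were seen on other chromosomes. On chromosome 16 every such run lay above 0 (lowest 0.05), and 49.0% lay above 0.30, a share that its median of 0.29 makes likely. On chromosomes 9 and 15 runs lay on both sides of 0, with 34.4% above 0.30 on chromosome 9 and 28.6% below −0.30 on chromosome 15. Copy number was not measured, and a line effect and a genotype effect stay open.

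Arrays 1 and 2 deviated more alike than the other pairing of opposite dyes, as did arrays 3 and 4. The spread between these pairs was 2.86 times that of the other pairing by median absolute deviation but 1.24 times by SD, and it restates the values that showed the pattern, so noise of single arrays stays open. A different culture or RNA extract behind each pair would change biological gene groups, and 4 of 24 lists differed between the pairs (camera, adjusted p under 0.05), but 0 did with an estimated correlation, so this cannot be told apart from a technical difference. In limma 0 genes differed between the pairs after adjustment, but this fit leaves 1 residual degree of freedom and could hardly call any. At an unadjusted p under 0.05 stood 1895 and 1439 of 14222 genes in the 2 directions, a larger share than chance gives at that threshold.

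Hox genes changed in both directions, and noise of dim spots, as the whole source, would turn the sign of about 1 in 2 genes between arrays. Of 17 Hox genes at 2-fold or more on arrays 1 and 2, blanks on other arrays allowed, 1 turned sign on arrays 3 and 4 (exact binomial test against 1 in 2, one-sided p = 0.000137). It was Hoxd10, named outside the naming rule, and noise in such single genes stays open. Many of the other genes, such as Hoxc9 and Hoxb5, had already passed the main fit of these same arrays, so their agreement was known beforehand. Genes of one Hox cluster are also not independent, so the p-value adds no support beyond the count. A different body position of origin of the 2 lines would also change other patterning factors, and 59.0% of these changed 2-fold or more, against 14.2% of other genes (Fisher's exact test, odds ratio 8.65, two-sided p = 1.35e-10). Loss of Mll1 predicts such a change too, so position and genotype cannot be told apart with 1 comparison of lines.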

How the results depend on the processing

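4 alternatives were chosen after seeing the data: values on 3 or 4 arrays, arrays 1 and 2, and 3 and 4, as a random block, chromosome 14 left out, and each gene relative to its chromosome's median. Kmt2a kept its direction and call in every alternative run, with log2 ratios from −1.46 to −1.04. No named gene reversed. Each had one sign on all 4 arrays, so leaving out, averaging or rescaling arrays could not turn it. With 1 array left out, 16 of 99 named genes lost the call in at least 1 case (up to 10 per array). Under the random block 11 lost it, namely Tyms, Cdkn1c, Oasl1, Cx3cl1, Nkd1, Meg3, Per3, Zfy2, Mef2c, Myog and Alpl. The block's pair correlation of 0.73 was a trimmed mean over genes, not limma's own estimate, and the number of calls lost may depend on that choice. With arrays 1 and 2, and 3 and 4, averaged, Des, Cx3cl1 and Zfy2 lost the call. Other alternatives cost at most 3. Genes higher numbered 2690 with arrays 1 and 2, and 3 and 4, averaged, and 2532 to 2860 with 1 array left out, where fewer arrays enter the fit. All other counts of genes, 2-fold counts included, stayed within 1.5 times. Of 2043 genes changed 2-fold or more, 1997 were also called with those pairs averaged and 1856 under the random block.

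For list calls, the cause was not tested. With an estimated correlation the Hox, extracellular matrix, smooth muscle and adipocyte lists all had an adjusted p of 0.846. With arrays 1 and 4, and 2 and 3, averaged, it was 0.0848 for Hox genes and extracellular matrix and 0.0862 for adipocyte markers, which had 0.0692 under scaling. Relative to chromosome medians, Hox genes had 0.0545. With each probe by itself, extracellular matrix lost its call and its direction turned without passing (0.989). CDK inhibitors and p53 targets (4.07e-05), imprinted genes (0.0371), neural markers (5.57e-11) and cartilage and bone markers (0.00147) passed. Genes with several features then count more than once. The inflammatory list passed with arrays 1 and 2, and 3 and 4, averaged (0.0352) and without chromosome 14 (0.0354). With 1 array left out it ranged from 0.0273 to 0.110 and adipocyte markers from 0.0240 to 0.0520. Fry, which makes no comparison with other genes, passed the circadian list downward (0.00837), where camera had an upward direction that did not pass (adjusted p = 0.970). Fry also passed patterning factors (0.00702), cell cycle (0.00360), CDK inhibitors and p53 targets, inflammation and housekeeping (each 0.00826), interferon (0.0381), Wnt, endothelial and muscle markers (each 0.00457), epithelial (0.0229), neural (0.00255) and cartilage and bone markers (0.00116).

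The zero filters moved nothing, as no value was exactly 0, so they show nothing about stability. List tests were not run under the random block. Without intensities, signal over background sets a limit on the ratios that is unknown here.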

Other observations

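Several Hox genes outside the main test had a value on 3 arrays. Allowing 1 blank (a choice made after seeing the data), 28 Hox genes could be tested, of which 7 rose and 16 fell. The genes gained, named after their values were seen, include Hoxd8 (log2 ratio 6.32, limma adjusted p = 0.00221) and Hoxd4 (4.17, adjusted p = 0.0129), both higher, and Hoxc8 (−3.70, adjusted p = 0.00589) and Hoxa10 (−5.09, adjusted p = 0.0433), both lower. Together with Hoxd9, all Hoxd genes that could then be tested had ratios above 0, and all Hoxc genes ratios below 0. Hoxb13 had a fitted ratio of 0.99 (adjusted p = 0.0112) although 2 of its 3 values lay below 0, because the dye term weights a lone array more, and Hoxb1 was at 0.01. Of the 39 Hox genes, 37 were named on the array. Of these, 15 were outside the main test, and 2 of the 15 had no value on any array.

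Among 229 groups of at least 8 genes sharing a symbol stem, formed after seeing the data, 1 passed camera's test. The clustered protocadherin genes Pcdhb, cell-adhesion molecules, fell in 11 of 13 cases with a median of −1.35 (adjusted p = 0.0215, and adjusted p = 0.969 with an estimated correlation). Pcdhb20, picked after its value was seen, was at −4.14. The next groups by adjusted p were Pex genes of peroxisomes, of which 11 of 14 were lower (adjusted p = 0.0963), and Cyp genes, of which 20 of 44 were lower (adjusted p = 0.103). Serpinb genes had a median of −1.40 with 9 of 14 lower, Lce genes of the skin barrier a median of 1.79 with 6 of 10 higher, and 8 of 12 Hspa chaperone genes were higher, but none of these 5 groups passed (for the last 3, adjusted p = 0.133, 0.133 and 0.129).

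Of 5012 features without a gene symbol and with a value on all arrays, 240 were at least 2-fold higher and 281 at least 2-fold lower (limma).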
